A study of Mus musculus with 2 samples.

How the data were processed

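Gene expression was measured on 2 oligonucleotide arrays, each hybridised with biotin-labelled cDNA made from total RNA of a mouse embryonic stem cell line (i-OSKM-ESC, strain 129 background). One array held RNA of cells given doxycycline at 4 µg/mL and collected 24 hours later, and the other held RNA of cells that received fresh medium without the drug. Each group has 1 array, so there is no replicate in either group and no test between the groups could be made.

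The deposited table holds 1 log2 value per probeset and array, 35556 probesets in all. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, a procedure that corrects background, equalises the arrays and summarises the probes of each probeset. Versions, genome build and annotation are not given in the sources used here. The deposited values ran from 2.49 to 14.2 in the array labelled plus doxycycline (median 6.49) and from 2.49 to 14.2 in the array labelled no doxycycline (median 6.47), which is the range of RMA values on a log2 scale, and they were used as deposited. RMA aligns the distributions of the arrays, so a change shared by most transcripts would not be visible, and its values compress the fold changes of dim transcripts. The table gives no detection call, so a level near the bottom of the scale cannot be told from background.

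Probesets were named from the platform annotation supplied with the series. Of the 35556 probesets, 21789 were assigned to exactly 1 gene, 1621 to several genes and 12146 were not listed. Of the 21789, 21698 had a gene identifier present in the mouse gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table was used only for symbols and for the order of genes along a chromosome. The array files name no genome build, so no coordinates are given. The value of a gene was the mean of the probesets assigned to it alone, which gave 19938 genes, 18939 of them with 1 probeset. Probesets with several genes and unlisted probesets entered no gene's value.

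The comparison was the difference of log2 values, plus doxycycline minus no doxycycline. A gene passed the expression filter when the higher of its 2 values reached the median of all values in the table (6.48), and 11191 genes passed. A gene was called higher or lower when it passed the filter and differed at least 2-fold. Because no replicate error exists, the spread was described in 2 other ways. Genes were sorted into 20 bins of mean expression, and the robust SD of the differences (1.4826 times the median absolute deviation) was taken in each bin. For genes with 2 probesets passing the filter, the SD of a probeset's difference within its gene was computed. Neither is an error between cultures.

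Before the data were examined, 27 gene lists with 504 genes were fixed, along with the filter, the 2-fold rule, the alternatives and the rule for naming genes. The rule names the 4 induced factors, the 12 genes with the largest rise and the 12 with the largest fall among genes called (leaving out predicted, small RNA and olfactory or vomeronasal receptor symbols), up to 4 members of each list with the largest difference among those passing the filter, and the housekeeping genes. Probesets of exactly 1 gene covered 471 of the 504 list genes, and the other 33 were not analysed here. For each list of at least 5 measured genes (26 lists) the median difference over all measured members was placed among 10000 random lists of the same size, matched on mean expression by the 20 bins. A list was said to stand apart at or below the 2.5th or at or above the 97.5th percentile. These percentiles describe the 2 arrays and are not p-values. If the genes of a list varied independently, about 1 in 20 lists would stand apart by chance, or 1.3 of 26. The random lists do not allow for genes that move together, with which more lists can fall outside.

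The steps were tested on simulated data for this comparison, with 19938 genes given noise of the spread measured in each bin and 200 of them changed. The 2-fold rule recovered 50 of 50 genes changed 3-fold and 2 of 50 changed 1.5-fold, and it called 1 of 10559 unchanged genes. Of 100 lists of 20 genes, 3 stood apart with no shift, 92 with a log2 shift of -0.2 and 100 with a shift of -0.4. The noise was normal, independent between genes and scaled by the robust SD, which leaves out extreme differences. It held no variation between cultures, so these numbers check the steps and give no rate of false calls in the data.

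Alternatives were other filters, a loess trend on mean expression removed from the differences, quantile normalization of both columns, an offset of 32 added on the linear scale, the brightest probeset of each gene, all probesets counted one by one, a 1.5-fold threshold, and for the lists a 20% trimmed mean, unmatched random lists, members passing the filter, and leaving out the most changed member. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.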

Results

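The samples came from i-OSKM-ESC, mouse embryonic stem cells derived from the KH2 line and engineered so that doxycycline, a tetracycline antibiotic used as a gene switch, turns on Oct4, an epitope-tagged Sox2, Klf4 and c-Myc, the transcription factors used to reprogram somatic cells. The transcripts of cells exposed to 4 µg/mL doxycycline for 24 hours were compared with those of cells left without it, on 1 whole-transcript array per condition. The question was how forced expression of the 4 factors changed gene expression in cells that already express them. Each value below comes from 1 array per group with no replicates, so no difference carries a replicate error or a p-value, and the number of arrays limits the precision. No culture of the parental line with doxycycline was analysed here, so an effect of the drug itself and an effect of the factors are not separated. The 2 arrays correlated across the 19938 genes with a Pearson r of 0.989, where genes are not independent replicates.

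The induced factors were examined first. Sox2 was 2.01-fold lower in the array labelled plus doxycycline, with a log2 value of 10.88 against 11.89. Pou5f1, which encodes Oct4, was 1.33-fold higher (12.46 against 12.05). Klf4 was 1.34-fold higher (9.34 against 8.91) and Myc was 1.28-fold higher (10.42 against 10.07). Among genes of like mean expression, the difference of Pou5f1 lay at percentile 96.9, that of Klf4 at 96.1, that of Myc at 94.6 and that of Sox2 at 0.401. Each factor has 1 probeset, and whether its probes lie in the part of the transcript that the transgene carries is not given in the sources used here. Sox2 lay at the 2-fold threshold, with a log2 difference of -1.01 that became -0.996 with an offset of 32 on the linear scale. If the probes read the transgenes, the lower value of Sox2 runs against the label and the higher values of the other 3 go with it. If they read only the endogenous transcripts, neither direction checks the label. The factors therefore do not settle the label. All directions below rest on the labels of the arrays.

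Of the 11191 genes that passed the expression filter, 103 were at least 2-fold higher and 86 at least 2-fold lower in the array labelled plus doxycycline, 1.69% of genes in all. The largest rise was that of Fah, the last enzyme of tyrosine breakdown, at 8.04-fold (log2 10.65 against 7.65). Tgm2, a protein-crosslinking transglutaminase, was 7.11-fold higher and Atp2a3, a calcium pump of the endoplasmic reticulum, 5.49-fold higher. The inhibitory Fc receptor gene Fcgr2b was 4.49-fold higher, the growth factor gene Fgf18 4.43-fold higher and the epithelial membrane protein gene Emp1 4.40-fold higher. Id2 and Id1, which encode inhibitors of basic helix-loop-helix transcription factors, were 4.10-fold and 3.61-fold higher. The semaphorin receptor gene Plxnc1 was 3.49-fold higher (log2 difference 1.80, or 1.11 with an offset of 32 on the linear scale), Mfsd6 3.37-fold, the simple-epithelium keratin Krt8 3.36-fold and Dkkl1 3.18-fold.

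Among the genes at lower level, Upp1, which encodes uridine phosphorylase, differed most when a gene was measured by the mean of its probesets, at 5.19-fold (log2 8.90 against 11.28). Elobl was 4.90-fold lower, Mcf2 4.26-fold lower, and the ectonucleotidase gene Enpp3 4.00-fold lower. Dnmt3a, a de novo DNA methyltransferase, was 3.68-fold lower (8.08 against 9.96). Bnip3, which acts in mitophagy and has 2 probesets, was 3.49-fold lower (log2 difference -1.80), but by its brightest probeset it had -2.41, beyond the -2.37 of Upp1. The arginine methyltransferase gene Prmt8 was 3.42-fold lower, the fatty acid transporter gene Slc27a2 2.86-fold lower and the secreted phospholipase gene Pla2g10 2.72-fold lower. Mkrn1-ps1 was 2.98-fold lower and its parent gene Mkrn1 2.60-fold lower, and hybridisation of one transcript to both probesets was not excluded. The imprinted long noncoding RNAs Meg3 and Rian were 2.88-fold and 2.86-fold lower.

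**Figure D1:**
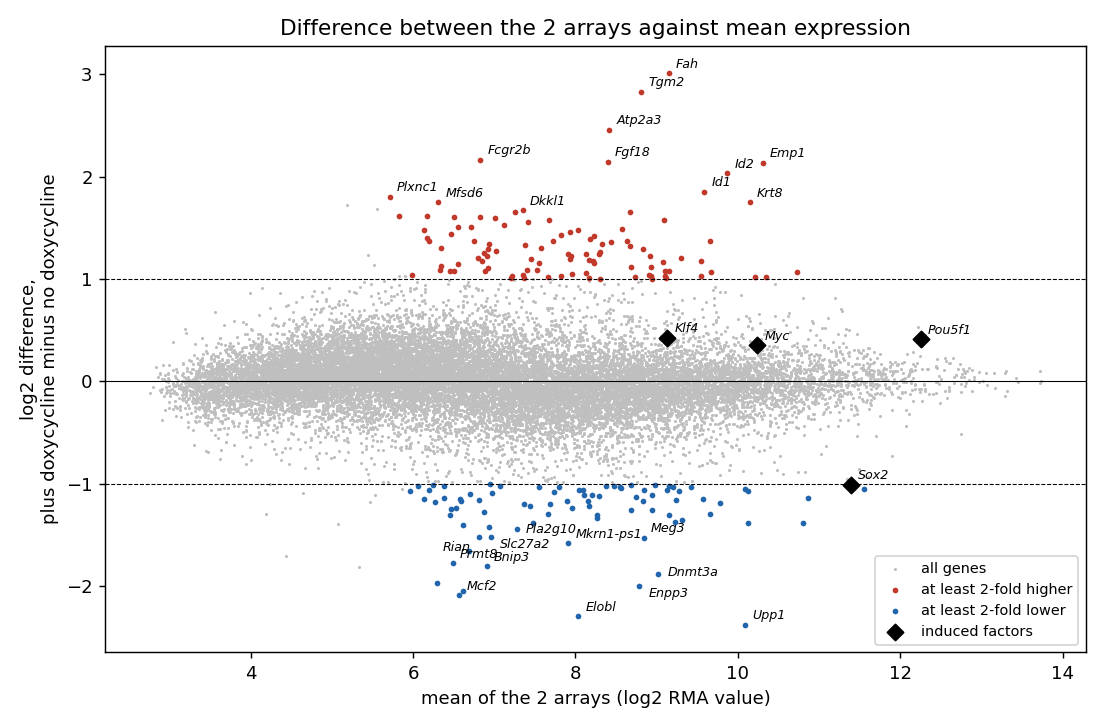
Log2 difference (plus doxycycline minus no doxycycline, vertical axis) against the mean log2 RMA value of the 2 arrays (horizontal axis), 1 point per gene, with dashed lines at 2-fold. The 103 genes called higher are red and the 86 called lower are blue, the 4 induced factors are black diamonds, and Sox2 lies at -1.01 while the other 3 lie between 0.35 and 0.43.

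The size of these differences can be set against the spread of differences across genes and between probesets of a gene. The spread across genes holds any response of the cells as well as noise, and it is not an error between cultures. The robust SD of the log2 differences was 0.246 over genes passing the filter, and by expression bin it lay between 0.161 and 0.297. For the 492 genes with 2 probesets passing the filter, the SD of a probeset's difference within its gene was 0.167, and the paired differences correlated across genes with a Pearson r of 0.695. Among probesets passing the filter, 1.60% of the 12409 with 1 gene differed at least 2-fold. The share was 0.249% of 803 probesets with several genes, 3.68% of the 3398 unnamed probesets whose identifiers come before the first named one, and 1.09% of the 2022 other unnamed probesets.

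Genes of the naive pluripotency list, which maintain or mark embryonic stem cells of the preimplantation type, were lower as a group. The median log2 difference of the 24 measured genes was -0.44, below all 10000 random lists (percentile 0), and 18 of 24 differences were negative. The Krüppel-like factor genes Klf5 and Klf2 were both lower, by 2.61-fold and 2.60-fold, and the homeobox gene Gbx2 was 2.25-fold lower. Dppa2, named after its value was seen, was 2.10-fold lower. Tcl1, a coactivator of Akt kinase, was 2.30-fold higher, and 18 members passing the filter were under 2-fold. The core factor gene Nanog, chosen after its value was seen, had a difference of -0.13, and Esrrb and Zfp42, chosen likewise, had -0.44 each.

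The list of genes bound by Oct4 and Sox2 had a median of -0.43 over 10 measured genes, also at percentile 0. Mycn, the Myc paralog of embryonic stem cells, was 2.59-fold lower and Fbxo15 2.38-fold lower. Lefty2, an inhibitor of Nodal signalling, was 2.26-fold higher (log2 difference 0.92 with the offset, under 2-fold). Utf1, at -0.95, stayed under 2-fold. The primed epiblast list, with genes of the later, postimplantation state, had a median of -0.26 over 13 genes, at percentile 0.515. Its 3 lower members were Dnmt3a, the transcription factor gene Otx2 (2.47-fold) and Dnmt3l (2.46-fold), a cofactor of de novo methylation. With the offset, Otx2 had -0.95 and was no longer 2-fold lower. Zic2 had a difference of -0.55. Without Dnmt3a the list lay at percentile 10.7 and did not stand apart. Beside these lower lists, the fibroblast and feeder cell list was higher, with a median of 0.19 over 30 genes (percentile 99.9), although 0 of the 17 members passing the filter reached 2-fold. Among the members passing the filter, the largest differences were those of Zeb1 (-0.64), Fbln2 (0.52), Col1a2 (0.50) and Col5a1 (0.45). With only members that passed the filter its median was 0.13, at percentile 95.5, and after loess centring the median was 0.11.

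Lists for early lineages gave medians near 0. Few members were called, except that 2 of the 11 neuroectoderm members passing the filter were higher and 1 was lower. Over all genes passing the filter, 1.69% were called. The trophectoderm list had a median of 0.08 (percentile 82.1), and of its 15 members passing the filter only Krt8 was 2-fold higher. Tead4, a transcription factor of the trophectoderm, had a difference of 0.98, Peg10 of -0.85 and Tfap2c of -0.83. Krt18, the usual partner of Krt8 and named after its value was seen, differed by 0.08. The primitive and visceral endoderm list had a median of 0.04 (percentile 67.4) with 0 of 18 members called, and Cubn was its most different gene at -0.93, followed by Apoa1 at 0.50, Sparc at -0.44 and Pdgfra at -0.43. The primitive streak and mesoderm list had a median of 0.10 (percentile 75.9) with 0 of 13 called, and its members included Bmp4 at 0.93, Msx1 at 0.53, Hand1 at 0.30 and Eomes at -0.24. In the neuroectoderm list, with a median of 0.03 (percentile 50.4), the neuronal cytoskeleton genes Map2 and Tubb3 were 2.52-fold and 2.41-fold higher, while the transcription factor gene Neurod1 was 2.12-fold lower (-0.94 with the offset, under 2-fold) and Olig2 had -0.78.

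The keratinocyte list stood apart upward, with a median of 0.28 over 19 genes (percentile 99.98) and 17 positive differences. Krt17 was its called member, 2.33-fold higher (0.96 with the offset, under 2-fold), while Perp, a desmosome protein gene, had 0.85, Sfn 0.81 and Lgals7 0.48, and 13 members lay below the expression filter. The median was 0.64 over the 6 members passing the filter, 0.13 with the offset and 0.20 after loess centring. Over all genes, the median difference varied with mean expression, from 0.11 in a bin of dim genes to -0.09 in a brighter bin. The keratinocyte percentile allows for this trend, but the count of positive differences does not. The epithelial list had a median of -0.14 (percentile 4.01). Its called member was the desmoplakin gene Dsp, 2.12-fold higher (0.92 with the offset, under 2-fold), whereas Crb3 had 0.74, Cldn6 -0.52 and Spint1 -0.49. The germline list was lower, with a median of -0.16 over 16 genes (percentile 0.59) and of -0.26 over the 10 passing the filter, 0 of which were called, and Dazl (-0.88), Mael (-0.86), Hormad1 (-0.68, or -0.40 with the offset) and Stra8 (-0.53) differed most. The 2-cell-stage list, of which 7 of 16 genes were measured, had a median of 0.01 (percentile 48.1), and Usp17ld, its one member passing the filter, had -0.68. Usp17ld belongs to a family of close copies, so its value is uncertain.

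**Figure D2:**
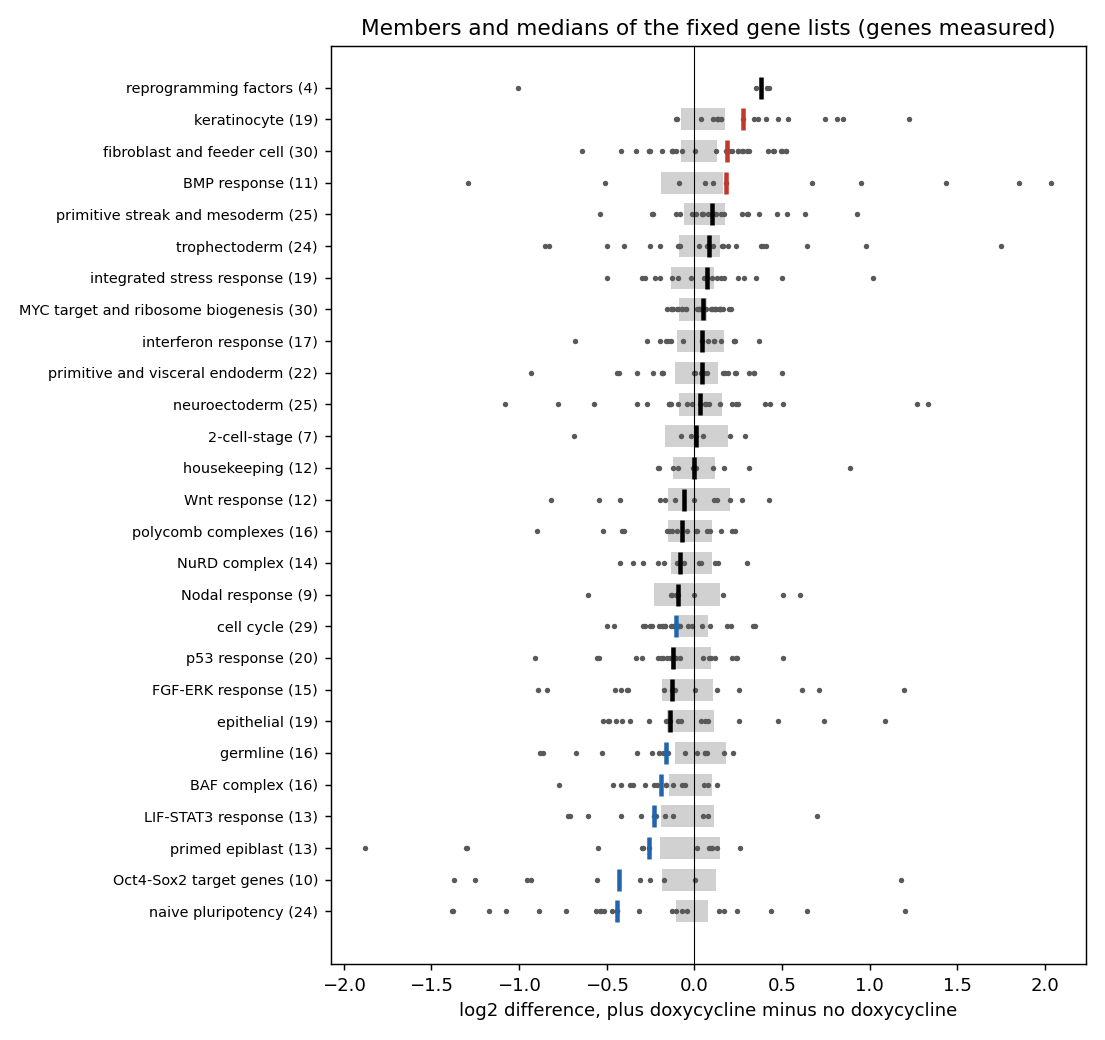
Log2 difference (plus doxycycline minus no doxycycline, horizontal axis) of the measured members of each fixed list (grey points) with the list median (bar; blue where it stands apart low, red where high) and the range of 95% of random lists matched on expression (grey band; none for the 4 induced factors). The medians of the naive pluripotency and Oct4-Sox2 target lists, at -0.44 and -0.43, lie outside their bands.

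Signalling lists moved in different directions. In the BMP response list 3 members were called higher and 1 lower, with a median of 0.18 over 11 genes (percentile 98.5). The higher genes were Id1, Id2 and Id3 (2.71-fold), and the lower gene was Smad7, an inhibitor of the pathway, at 2.44-fold. Over members passing the filter the median was 0.39. Without Id2 the list lay at percentile 95.9, and with an offset of 32 on the linear scale at 93.8. The LIF-STAT3 list, which covers the cytokine pathway that keeps mouse embryonic stem cells undifferentiated, had a median of -0.23 (percentile 0.58) with 0 of 12 members called. The LIF receptor gene Lifr had -0.72, Icam1 -0.71, Stat3 -0.61 and the co-receptor gene Il6st -0.42. In the FGF-ERK list (median -0.13, percentile 9.97) Phlda1 was 2.29-fold higher, and the feedback inhibitors Dusp6 (-0.89) and Spry2 (-0.84) opposed Spry4 (0.71). The Wnt list had a median of -0.06 (percentile 17.6), with Fzd7 at -0.82, Dkk1 at -0.54, Axin2 at -0.43 and Wnt5b at 0.27. The Nodal list had a median of -0.09 (percentile 30.3), with Nodal at -0.60, Foxh1 at 0.51, Skil at 0.16 and Ski at -0.14. The interferon list had a median of 0.04 (percentile 57.2), with Irf9 at -0.27, Stat2 at -0.16, Ddx58 at -0.15 and Bst2 at 0.11.

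Lists of MYC targets, growth and stress showed small differences. The 30 MYC target and ribosome biogenesis genes, many of them used to make ribosomes, had a median of 0.05 (percentile 91.6), and all lay between the values of Tfrc (-0.16) and Odc1 (0.21), with Hspd1 at 0.20 (0.12 by its brightest probeset) and Srm at 0.17. The cell cycle list had a median of -0.11 over 29 genes (percentile 0.605), 23 of them negative and 0 called, and its members included Cdkn1b (-0.50), Cdc6 (-0.46), Ccnd3 (0.35) and Rrm2 (0.33). The p53 list had a median of -0.12 (percentile 3.85), with Plk3 at -0.91, Sesn1 at -0.54, Trp53inp1 at -0.33 and Phlda3 at 0.50. In the integrated stress response list (median 0.07, percentile 90.8) the stress-induced gene Nupr1 was 2.03-fold higher (0.95 with the offset, under 2-fold), and Aldh18a1 had 0.50, Ddit4 -0.50 and Ddit3 0.35.

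Among chromatin complexes, the BAF remodelling complex was lower as a list, with a median of -0.19 over 16 genes (percentile 0.57), 13 negative differences and 0 of 15 members called. Smarcc2 had -0.77, Smarcd3 -0.46, Arid1a -0.42 and Arid1b -0.37. The NuRD complex, a remodelling and deacetylase complex, had a median of -0.08 (percentile 11.6), with Chd3 at -0.43, Mbd3 at -0.35, Hdac2 at 0.30 and Mta1 at -0.29. The polycomb list had a median of -0.07 (percentile 22.2), with Phc1 at -0.90, Kdm2b at -0.52, Cbx7 at -0.41 and Aebp2 at -0.40.

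The housekeeping genes had a median of -0.0024 over 12 genes (percentile 49.4). Differences were 0.11 for Actb, 0.17 for Hprt, -0.01 for Tbp, -0.12 for Ppia, -0.0033 for Rplp0, -0.20 for Pgk1, -0.09 for Sdha, 0.31 for Ywhaz, -0.0014 for Gusb, -0.21 for Polr2a and 0.01 for Eef2. B2m, the light chain of class I histocompatibility molecules, had 0.89. Of the 26 lists with a percentile, 7 stood apart low and 3 high. With independent genes, 1.3 would be expected outside. Genes of a list can move together between cultures, so these counts measure no excess over chance.

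Meg3 and Rian lie near each other in the gene order, in an imprinted domain that runs from Dlk1 to Dio3, and the domain was examined after their values were seen. The values of 39 of its 45 measured noncoding genes were negative, with a median of -0.59. Only 21 of the 45 passed the filter, and 7 of these were at least 2-fold lower, against 86 of the 11191 genes in all. The 3 protein-coding genes of the domain had positive differences, 0.85 for Dlk1, 0.64 for Rtl1 and 0.89 for Dio3. Rtl1 and Dio3 lay below the expression filter. The 20 nearest measured neighbours, 10 on each side, had a median of 0.13. Noncoding genes of the domain may vary together, so the 45 are not separate observations.

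**Figure D3:**
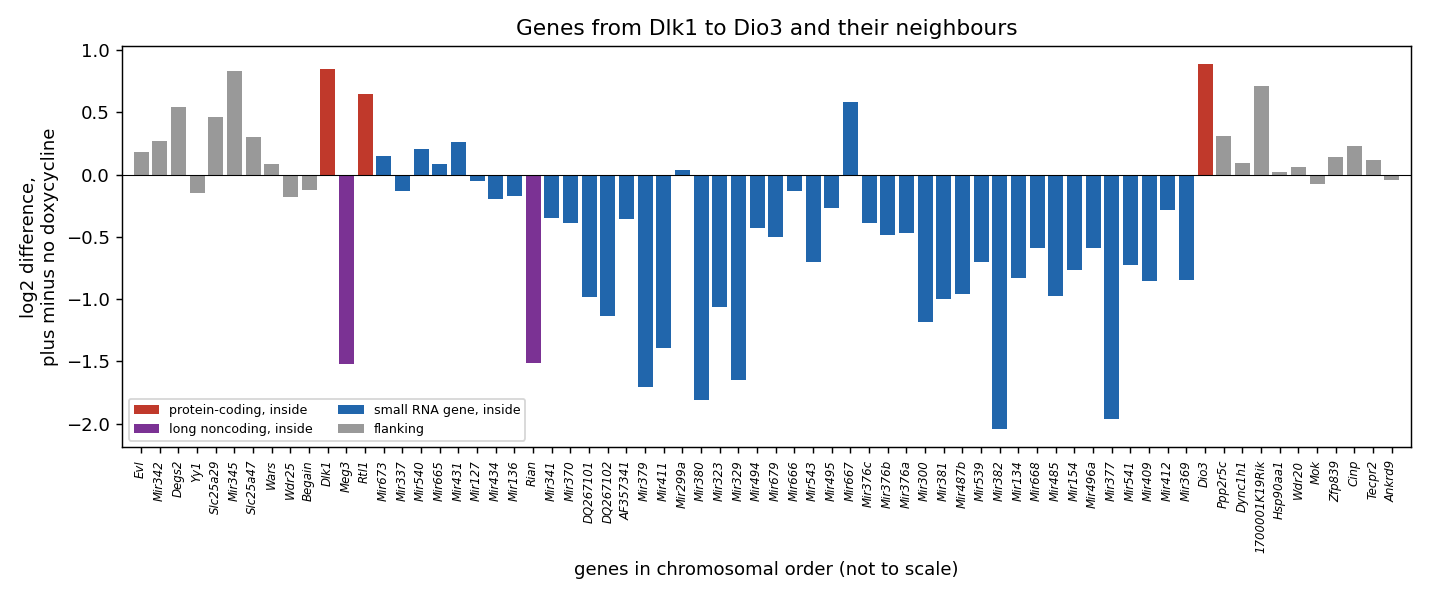
Log2 difference (plus doxycycline minus no doxycycline, vertical axis, bars from 0) of each measured gene from Dlk1 to Dio3 and of 10 neighbours on each side, in chromosomal order and not to scale, with 1 array per group and no error bars. Protein-coding genes of the domain (red) are above 0, Meg3 and Rian (purple) are at -1.52, and 39 of the 45 noncoding genes (purple and blue) are below 0.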

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

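The tests of explanations in this part were chosen after the values they concern had been seen, while the offset of 32 had been chosen before.

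Sox2 was 2.01-fold lower in the array labelled plus doxycycline, while Pou5f1, Klf4 and Myc were at most 1.34-fold higher, although the label says that all 4 were induced. Sox2 lay at the threshold and was at -0.996 with the offset of 32, under 2-fold. If the arrays had been exchanged and the probes read the transgenes, all 4 factors would be lower, but 1 was. The other 3 had a median of 0.41 (percentile 99.5 of random lists). They were left after the lower one was set aside, and lists under 5 genes otherwise got no percentile, so this percentile carries no weight. The set is split and leaves an exchange open. Whether signal near the top of the scale hides a rise of Pou5f1 also stays open, because the largest rise among the 111 genes at least as bright in the control array was 0.51, but 5 of the 997 genes in the brightest bin differed 2-fold in either direction, too few to test it. Such a limit, if shared by all probesets, is argued against between the control level of Klf4 and 0.5 above that of Myc. In that range, 9 genes were at least 2-fold higher. They were not counted for Klf4 and Myc apart, and a limit of a single probeset was not tested. Probes outside the transgene, and repression of the endogenous genes by the induced proteins, stay open because the probe positions are not given in the sources used here.

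Unnamed probesets, which enter no gene's value, gave 48 at least 2-fold higher and 99 at least 2-fold lower among 5420 that passed the filter. Of these, 43 higher and 82 lower probesets belonged to the 3398 whose identifiers come before the first named one.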

How the results depend on the processing

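Every alternative reported here was planned. The 103 genes higher and 86 lower became 57 and 52 with the filter at the 75th percentile, 66 and 49 with an offset of 32, and 363 and 425 at 1.5-fold, changes that follow from the construction of these settings. Counting all probesets one by one gave 154 higher and 193 lower, and the added unnamed probesets account for 48 and 99 of these. With no filter the counts were 110 and 94, with loess-centred differences 115 and 77 (102 and 72 of the main calls were shared), with quantile-normalized columns 114 and 72, and with the brightest probeset 105 and 86. The share of called genes that were higher, 54.5%, was 59.9% after loess centring and 61.3% after quantile normalization, but 44.4% with all probesets one by one and 46.1% at 1.5-fold, where lower calls outnumbered higher ones. Of 181 list percentiles under an alternative, 173 stayed on their side of the limits, and of the 8 that did not, 5 lost their place outside the limits and 3 gained one. The primed epiblast list reached 10.7 without Dnmt3a. The fibroblast and feeder cell list reached 95.5 with members passing the filter and 96.8 with the trimmed mean. The BMP list reached 93.8 with the offset and 95.9 without Id2. The epithelial list (1.18) and the p53 list (1.69) stood apart only against unmatched random lists, and the integrated stress response list (98.0) only with members passing the filter. Some medians of lists that stood apart moved by over 1.5 times, to 0.09 with the offset and 0.12 with the trimmed mean for the fibroblast list, to 0.10 and 0.47 for the BMP list, and to -0.12 without Dnmt3a for the primed epiblast list. Lists that did not stand apart had values near 0, and some changed sign. The Nodal list went from -0.09 to 0.03 with the trimmed mean, and the interferon list from 0.04 to -0.15 with members passing the filter. After loess centring the neuroectoderm list went from 0.03 to -0.05 and the integrated stress response list from 0.07 to 0.004. Beyond what each setting's construction shows, the cause was not tested. The 2-cell-stage list could not be run with members passing the filter, since fewer than 5 remained. The 4 factors moved by less than the spread at like expression in 12 of 12 checks, but Sox2, at -0.996 with the offset, was then under 2-fold. Of other named genes, 380 of 387 values kept their side of 2-fold, 6 dropped under it with the offset (Lefty2, Otx2, Neurod1, Dsp, Krt17 and Nupr1) and 1 passed it (Tead4, 1.04 after loess centring). Some differences under 0.2 in size (Ski, Stat2, Ddx58, Bst2, Actb, Tbp, Rplp0, Gusb and Eef2) moved by over 1.5 times after loess centring. No paired analysis was possible because each group has 1 sample. No replicate could be left out for the same reason. With 1 array per group and no detection calls, dim genes near the filter are the least certain.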

Other observations

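Genes that were called but belong to no fixed list, chosen after their values were seen, are given here as values. Among those higher were Elavl3, a neuronal RNA-binding protein gene (2.78-fold), the axon growth genes Dpysl5 (2.69-fold) and Dpysl3 (2.53-fold), and the netrin receptor gene Unc5a (3.01-fold). Of cell surface and adhesion genes, Podxl was 2.98-fold higher, Nt5e 2.88-fold, Itga9 2.80-fold and Itgb3 2.42-fold. Dmgdh, an enzyme gene of dimethylglycine metabolism, was 3.07-fold higher and Bhmt2 2.58-fold higher. Pdk4, an inhibitor of pyruvate dehydrogenase, was 2.67-fold lower, the carbonic anhydrase gene Car2 2.52-fold lower and Ldhb, with 2 probesets, 2.24-fold lower. The transcription factor gene Klf8 was 2.44-fold higher, while Six4 was 2.45-fold lower and Etv1, with 2 probesets, 2.35-fold lower.

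The tests in the rest of this part were chosen after the patterns had been seen, except that of a trend with expression level in the imprinted domain, whose prediction preceded loess centring. The percentiles of the fixed lists and the loess, offset and left-out-member values of those lists had been chosen before the data were seen.

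The imprinted domain from Dlk1 to Dio3 showed noncoding genes lower (median -0.59, 39 of 45 negative) beside protein-coding genes higher. Noise of short RNA probesets is argued against, because the median of the domain's 43 small RNA genes, -0.59, lay below 10000 random sets (percentile 0). The sets were drawn from the 308 other small RNA genes, matched on expression, whose own median was -0.02. They do not allow for genes of a domain that vary together. A trend with expression level is also argued against, since the median after loess centring was -0.64. A candidate explanation is that the copies inherited from each parent moved apart, as Meg3 and Rian are expressed from the maternal copy and Dlk1, Rtl1 and Dio3 from the paternal one. The median of those 3 protein-coding genes, 0.85, goes with it, but they are few, 2 of them are dim, the 20 flanking genes also had a raised median of 0.13 (percentile 98.2), and 1 array per group cannot tell a response to the factors from a difference between cultures. The 8 microRNA genes before Rian had a median of 0.01 and the 32 after it one of -0.71, a contrast with no test.

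The largest rises (median 2.09 over the 12 named genes) and the lower naive pluripotency list were set against more fibroblast or feeder cell RNA in the array labelled plus doxycycline, whose fibroblast list had a raised median. As the whole cause of the differences within the naive list it is argued against. RNA of other cells, if it held none of these transcripts, would dilute all of them alike. Instead 12 of the 24 lay more than 2 spreads at like expression from the list median, from Klf5 at -1.38 to Tcl1 at 1.20. This scatter does not test whether dilution lowered the median of the list. For the largest rises the values cannot decide. The largest gain in linear signal among the 30 fibroblast genes was 124 (227 with its spread added), against a median gain of 843 for the 12 rises. Signals of different probesets are not on a common scale, and the 12 were picked for their rises. The collagen genes Col1a1, Col1a2 and Col3a1 had differences of 0.45, 0.50 and -0.07, Fn1 had -0.33 and Vim -0.10, and 12 of the 30 were negative. A part played by such RNA stays open for both patterns, as the fibroblast list lay at percentile 99.9. A trend with expression level is argued against for the naive list, whose median was -0.44 before and -0.43 after loess centring. A move toward the primed epiblast state would raise the primed list, but that list was lower, at percentile 0.515, or 10.7 without Dnmt3a, so these arrays give no sign of it and do not exclude it.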
